A study of Mus musculus with 21 samples.

How the data were processed

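The series held 21 arrays on which 2 sources of mouse total RNA were compared in the 2 channels of each array. The labels placed 4 arrays in the comparison of whole ovary with whole testis, 4 in 15 day against adult testis, and 4 in Spo11 knockout against wild type testis. A further 4 set whole testis, and 5 whole ovary, against a reference RNA. Each comparison had arrays in both channel orders, 2 and 2 in the groups of 4, and 3 and 2 in the group of 5. Spo11 encodes the enzyme that makes the DNA breaks of meiotic recombination. The array numbers in the titles fell into 5 runs. The knockout arrays all lay in run 1, the 15 day arrays in runs 2 and 5, and the arrays of the other comparisons in runs 3, 4 and 5.

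The deposited values were read as log2 ratios between the sources of RNA on an array, a unit that neither the labels nor the file headers stated. The reading rested on values of both signs centred near 0 and on extremes near the full scale of a 16-bit scanner on the log2 scale, of which the largest was 16.7. The authors' centring differed between arrays: the 6 arrays of runs 1 and 2 had a mean within 0.005 of 0 and a median above it, and the other 15 had a median of 0. No label described the scanning, the background correction or the dyes. Intensities and backgrounds were not used here, so dim probes could not be removed, and the number of arrays limits the precision. Whether arrays of a comparison held separate animals or separate extracts was not stated. The p-values of single probes and genes therefore measure only the spread between arrays, which may be technical. Tests that set a group of genes against other genes measure the spread between genes, and not that between animals either.

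The labels did not say which source stood on top of the ratio. Within every comparison, arrays of opposite channel order correlated positively across probes, with r between 0.471 and 0.925, so the submitters had already turned the values and no array was turned. The source named first in the comparison (ovary, 15 day, knockout, testis or ovary against the reference) was taken as the likely numerator. The basis was the ovary anchors Gdf9 and Zp2, which were fixed as anchors and are therefore no findings. In ovary against testis, Gdf9 was 1.00 ± 0.31 on the log2 scale and Zp2 0.30 ± 0.19; in ovary against the reference they were 0.94 ± 0.28 and 1.20 ± 0.17. The 0.30 of Zp2 did not pass the threshold, and the anchors also moved where no ovary was compared. In the knockout Gdf9 was at 0.90 ± 0.31 (not past the threshold without knockout replicates 1, 2 or 4, at 0.82, 0.89 and 0.82), Zp2 at -1.16 ± 0.19, and the untested probe of Zp3 averaged 1.89 (4 of 4 arrays above 0). That probe averaged 1.96 in ovary against testis (3 of 3 arrays above 0) and 3.60 in ovary against the reference (4 of 4). In testis against the reference Zp2 was at 0.49 ± 0.19 (not past it without testis against reference replicates 1, 2 or 3, at 0.45, 0.41 and 0.5). This basis is therefore weak. Tekt2, a gene of flagella, was at -4.68 in ovary against testis, which was seen only after the fit and points to the same numerator. Oaz3, the other tested haploid spermatid gene, points the other way, at 0.79 ± 0.25 in ovary against testis (0.70 and not past the threshold without replicate 4) and -2.12 ± 0.29 in testis against the reference (-1.40 without replicate 2). Early meiotic prophase genes, also seen only after the fit, go with Tekt2. Of 14, 12 fell and 0 rose in ovary against testis, and 12 rose and 0 fell in testis against the reference. The 10 tested oocyte genes do not, as 1 rose and 4 fell in ovary against testis. The testis anchors Prm1, Prm2, Tnp1 and Tnp2 were not named on the array and had 0 tested members. The sign of testis against the reference was tied to the others by the correlation of 0.947 between the direct and the indirect ovary to testis ratios. The signs of the 15 day and knockout comparisons rest on the same convention and on Tekt2, at -4.68 and -5.73 there, also seen only after the fit. Oaz3 did not pass the threshold in either of them. Turning the sign would turn every direction given here.

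Of 16128 probes, 9817 were annotated in the deposited platform table, and 9604 of those had exactly 1 gene symbol; 9496 matched the reference gene table by gene identifier. The 213 probes with several symbols and the 6311 not listed entered the probe counts only. Chromosomes came from the RefSeq gene table of the mouse assembly GRCm38.p6, and no coordinates were used. A probe was tested if it had a value on at least 3 arrays of each of the 5 groups, which 7561 probes did. Gene values were the mean per array over the tested probes of a symbol. This gave 4465 genes, 891 of them with several probes, with 119 genes on the X, 4302 on autosomes and 1 on the Y. No probe was named Spo11, so the knockout could not be checked on the targeted gene.

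Each array was centred on its median. The limma package (version 3.58.1, in R 4.3.3) fitted 1 model over the 21 arrays, with a coefficient for each of the 5 groups and a probe-specific effect of the channel that held the numerator. Moderated statistics were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was the threshold for a call. Errors are standard errors of that fit. The contrast of ovary against the reference minus testis against the reference gave the ovary to testis ratio through the reference. The contrast of the knockout minus the 15 day coefficient tested the difference of those effects. Named genes were chosen by a fixed rule: the 10 highest and 10 lowest genes past the threshold with the same direction on every array, without provisional symbols; up to 4 genes from each fixed list; the 10 largest X-linked changes; and the 5 largest differences each way between the knockout and 15 day effects.

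The 24 gene lists, the anchors and the rule for named genes were fixed before the data were examined. They held markers of germ cells (haploid spermatid, late spermatocyte, early meiotic prophase, spermatogonia, oocyte) and of other gonadal cells (Sertoli cell, Leydig and steroidogenesis, granulosa with theca and luteal, stroma and extracellular matrix, smooth muscle and peritubular, endothelium, macrophage and leukocyte, blood). Other lists covered adipose, epididymis, oviduct and ciliated epithelium, proliferation, the mitochondrial respiratory chain, sperm glycolysis isoforms, X-linked parents of testis retrogenes, autosomal retrogenes of those parents, ribosomal proteins, and the anchors of each sex. For each list, members past the threshold were counted with adjustment over all genes and over the list alone. Only part of each list was tested: 2 of 50 haploid spermatid, 7 of 29 late spermatocyte, 8 of 34 spermatogonial and 10 of 38 oocyte genes. The need for values in all 5 groups can leave out genes confined to 1 tissue. The camera test of limma compared each list with the other genes, with a preset correlation of 0.01 between genes and again with the correlation estimated from the list. Its p-values were adjusted over the lists of a comparison. The fry test, which asks whether a list moves on balance one way, was run on the 2131 genes with values on all 21 arrays. It does not set a list against the other genes, and its p-values were not adjusted. Its results are given for some lists where they part from camera. X-linked genes were set against autosomal genes with two-sided Fisher exact tests, adjusted over comparisons and directions. Their medians were compared by 100000 permutations of the chromosome labels over genes, two-sided. Genes are not independent replicates in any of these tests.

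The procedure was tested on simulated data with 7561 probes. In 1 comparison at a time, 67, 67 and 66 probes were changed by 1.5-, 2- and 4-fold. The noise was independent between probes, and the simulated arrays were not centred. A far larger share of probes was called in the real data, so the simulated shares need not carry over to them. At a change of 4-fold it recovered 92.4% of the changed probes in ovary against testis, 93.9% in 15 day against adult, 93.9% in knockout against wild type, and 71.2% in the knockout minus 15 day contrast. At a change of 2-fold these shares were 56.7%, 58.2%, 62.7% and 20.9%. Unchanged probes made up 9.38%, 6.61%, 6.67% and 4.62% of those called, and 3.39%, 5.71% and 4.82% for testis and ovary against the reference and ovary against testis through it, so in 4 comparisons the share lay above 5%. Alternatives covered the centring and scaling of arrays, the channel effect, separate fits, the filter on missing values, robust variances, array run as a random block, 1 probe in place of the mean, a 2-fold minimum, and leaving out each array. Log ratios beyond 10, and the 15 day arrays of 1 run at a time, were alternatives chosen after seeing the data. Files were read with the data.table package (version 1.17.8) and figures drawn with matplotlib (version 3.10.9).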

Results

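Total RNA of mouse gonads was compared on 21 arrays of 16128 probes: ovary with testis (4 arrays), 15 day with adult testis (4 arrays), Spo11 knockout with wild type testis (4 arrays), and testis (4 arrays) or ovary (5 arrays) with a reference RNA. An array carried values for between 6452 and 14012 probes. The array with the fewest was replicate 1 of ovary against testis. Values are log2 ratios with the source named first as the likely numerator, a direction inferred from ovary marker genes because the labels did not give it. Changes are relative to the median of each array, and errors are standard errors of the fit.

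The direct comparison addressed which genes differ between ovary and testis. Enzymes of steroid synthesis were among the genes most raised in ovary. Hsd3b1 was higher by 4.01 ± 0.67 (16.1-fold, n = 4 arrays) and Cyp11a1, which cleaves the side chain of cholesterol, by 3.24 ± 0.37 (9.45-fold, n = 4). The collagen Col3a1 was higher by 2.97 ± 0.40 (n = 4) and the inhibin subunit Inha by 2.85 ± 0.24 (n = 4). The genes most lowered in ovary included Cetn4 at -4.95 ± 0.26 (30.9-fold, n = 4), the synaptonemal complex gene Sycp1 at -4.75 ± 0.34 (n = 3), the tektin Tekt2 of flagella at -4.68 ± 0.31 (n = 4) and the heat shock gene Hspa4l at -4.49 ± 0.20 (n = 4). Each of these 8 genes went the same way on every array with a value.

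In ovary, 18 of the 24 tested genes of stroma and extracellular matrix rose and 1 fell (19 and 1 adjusted over the list alone), with a median of 1.08. Among them were Col6a1 at 2.80 ± 0.28 (n = 3), Mgp, an inhibitor of calcification, at 2.71 ± 0.22, and Col1a1 at 2.66 ± 0.23, while Pdgfra was the member that fell. All 7 smooth muscle and peritubular genes rose, also adjusted over the list alone, with a median of 1.25, led by Tpm1 at 2.43 ± 0.17 and Flna at 2.22 ± 0.14. Of 68 ribosomal protein genes, 49 rose and 1 fell (50 and 1 adjusted over the list alone), with a median of 0.82. The X-linked Rps4x and Rpl10 rose most, by 3.21 ± 0.16 and 3.05 ± 0.22. The member that fell, Rpl39l, was at -2.88 ± 0.29, whereas the X-linked Rpl39 was at 2.09 ± 0.28. These 3 lists stood above the other genes by camera, at adjusted p = 1.16e-07, 1.48e-05 and 9.40e-13. All 3 calls held with an estimated correlation, at adjusted p = 0.0141, 0.0141 and 0.0354, and no other list call of this comparison did.

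Genes of early meiotic prophase were lower in ovary: 12 of 14 fell and 0 rose, also adjusted over the list alone, with a median of -2.33. Psmc3ip, a partner of the meiotic recombinase, was at -3.90 ± 0.53 (n = 3), the synaptonemal Syce2 at -3.52 ± 0.19 and the meiotic cohesin Smc1b at -3.39 ± 0.20. The list lay below the other genes (camera adjusted p = 2.48e-05), but not past the threshold with an estimated correlation (adjusted p = 0.0797 with an estimated correlation). Of 7 late spermatocyte genes 4 fell and 0 rose, also adjusted over the list alone, among them the kinases Plk1 at -2.54 ± 0.36 and Aurkc at -2.38 ± 0.25, and the list did not pass (camera adjusted p = 0.135), though it did with 1 value in each group (adjusted p = 0.00353). The 2 tested haploid spermatid genes went opposite ways: Tekt2 fell, and Oaz3 was at 0.79 ± 0.25, a call that ended without replicate 4 of this comparison (0.70). Spermatogonial genes also went both ways, with Foxo1 at 2.84 ± 0.23 and Dazl, an RNA-binding protein of germ cells, at -2.26 ± 0.48 (n = 3). In that list 3 rose and 4 fell of 8, also adjusted over the list alone, and the median of -0.65 had the opposite sign to camera, which pointed up (adjusted p = 0.365). With probes on all 21 arrays the median was 1.3 and the list passed (adjusted p = 0.0366).

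Of 10 Leydig and steroidogenesis genes, 6 rose in ovary and 0 fell, also adjusted over the list alone, with a median of 0.91 (camera adjusted p = 0.0222; adjusted p = 0.117 with an estimated correlation; lost with probes on all 21 arrays). Of 9 granulosa, theca and luteal genes, 5 rose and 2 fell, also adjusted over the list alone, with a median of 1.30. Wnt4, a signal of ovarian development, was at 2.28 ± 0.38 and the hedgehog receptor Ptch1 at 1.65 ± 0.22 (n = 3). That list had the same camera values, 0.0222 and, as adjusted p with an estimated correlation, 0.117. It shares Cyp11a1 and Cyp17a1 with the Leydig list. Its median rests on Ccnd2 at 1.30 ± 0.15, whose 2 probes differed in sign; with 1 probe per gene Ccnd2 was at -0.09 and the list median at -0.085. Of 6 macrophage and leukocyte genes 4 rose and 0 fell, also adjusted over the list alone, including C1qc at 2.05 ± 0.30 and Lyz2 at 1.24 ± 0.27 (camera adjusted p = 0.0915; 0.0485 in a fit on these arrays alone). Sertoli cell genes were divided, 5 higher and 3 lower of 11, also adjusted over the list alone (median 0.03, camera adjusted p = 0.131; median -0.0374 without replicate 1, and 0.781 with adjusted p = 0.0445 on probes of all 21 arrays), with Wt1 at 1.51 ± 0.23 and the X-linked Rhox5 at -1.65 ± 0.31 (n = 3). Of 10 oocyte genes 1 rose and 4 fell, also adjusted over the list alone (median -0.64, camera adjusted p = 0.365), and with 1 value in each group the median turned to 0.59. Only these 10 of the 38 listed oocyte genes were tested, so the list does not show how oocyte genes as a whole differ. Padi6, which oocytes need for early development, rose by 1.82 ± 0.25 (n = 3), whereas Gtsf1, Kpna2 and Ddx4, which are also expressed in male germ cells, were at -4.08 ± 0.34, -2.51 ± 0.18 and -2.03 ± 0.32.

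At the level of probes, 4443 of 7561 passed the threshold between ovary and testis, 1935 higher and 2508 lower in ovary. Through the reference RNA, on 9 arrays that shared none with the direct comparison, 3432 probes passed, 1450 higher and 1982 lower. Across 4465 genes the direct and indirect ratios correlated at r = 0.947 (rho = 0.939), and 99.2% of the genes called directly had the same sign. Both called 715 genes higher, where independent lists would share 184.3, and 1241 lower, where they would share 484.7. Stroma and smooth muscle genes were again higher in ovary, with medians of 1.03 and 1.34, and both calls held with an estimated correlation (adjusted p = 0.0118 for each). Of 68 ribosomal protein genes 35 rose and 2 fell, and of 14 early meiotic prophase genes 10 fell and 0 rose, also adjusted over the list alone. These lists had medians of 0.63 and -2.27 (camera adjusted p = 1.72e-08 and 4.87e-05), and both calls were lost with an estimated correlation (adjusted p = 0.117 for each). Other lists called directly did not pass camera through the reference. They were Leydig, granulosa and X-linked parents of retrogenes (adjusted p = 0.0736 for each), oviduct (0.0804) and proliferation (0.12). A test in limma of direct minus indirect ratios called 0 probes, with 128 (1.69%) at an unadjusted p under 0.05; with all arrays scaled to 1 spread it called 64.

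**Figure D1:**
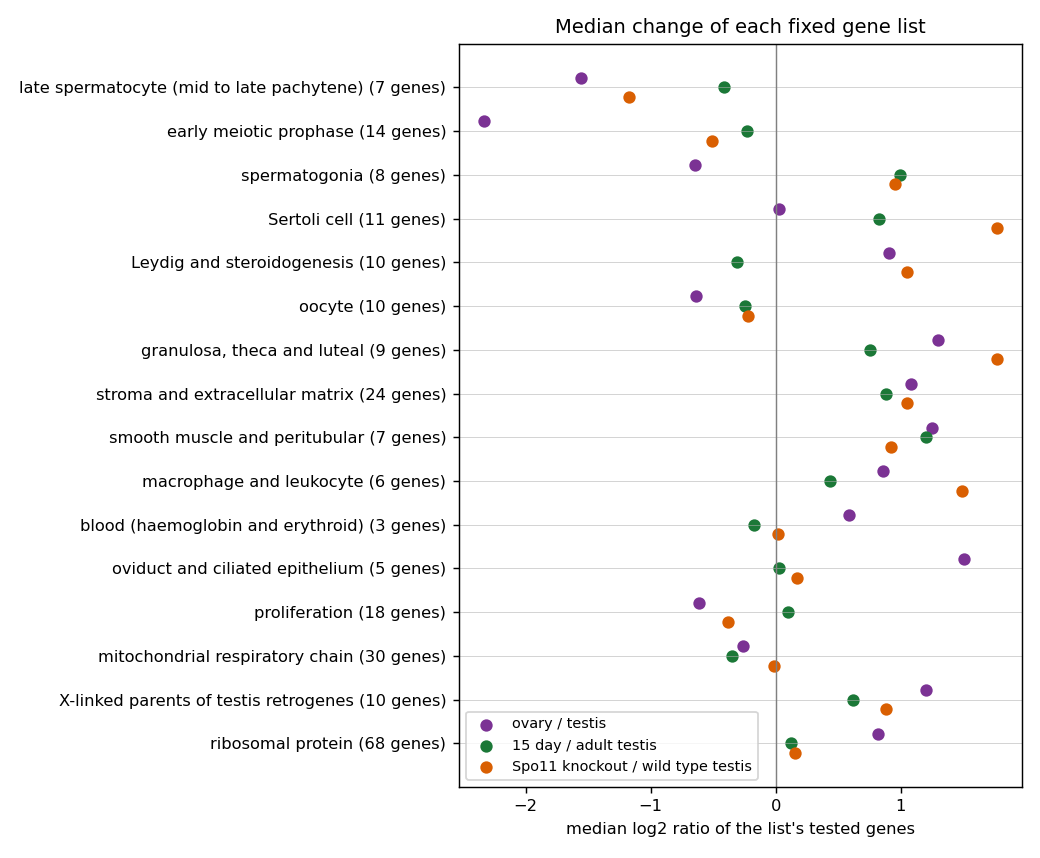
Median log2 ratio of the tested genes of each fixed list (x axis) in ovary over testis, 15 day over adult testis, and Spo11 knockout over wild type testis. Early meiotic prophase genes lie at -2.33 in ovary over testis, and Sertoli cell genes at 1.77 in the knockout comparison; several medians near 0, and those of spermatogonia, oocyte and granulosa genes in ovary over testis, turn sign in some alternative.

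Against the reference RNA, the genes most raised in testis included Tekt2, which was higher by 5.73 ± 0.31 (53.3-fold, n = 4), the testis isoform Cox6b2 of cytochrome oxidase by 5.54 ± 0.35 and Rsph1, of the radial spokes of axonemes, by 5.17 ± 0.32. Among the lowered genes the matrix gene Fn1 was at -3.93 ± 0.42 (n = 4), Col1a1 at -3.48 ± 0.23 and Krt18 at -3.30 ± 0.18. Of 24 stroma genes 2 rose and 18 fell (2 and 19 adjusted over the list alone), with a median of -1.49. Of 68 ribosomal protein genes 1 rose and 58 fell, also adjusted over the list alone, with a median of -1.09. Both lists lay below the other genes (camera adjusted p = 1.16e-06 and 1.82e-15), and both calls held with an estimated correlation (adjusted p = 0.0217 for each). So did that of the oviduct and ciliated epithelium list, of which 3 of 5 genes fell and 0 rose, also adjusted over the list alone (median -1.08, adjusted p = 0.0345 with an estimated correlation), though it was lost with all arrays scaled to 1 spread. The correlation of that list was estimated at 0, below the preset 0.01, so its holding was no stricter check. Early meiotic prophase genes rose in 12 of 14 cases and fell in 0, also adjusted over the list alone, with Sycp1 at 4.25 ± 0.30 and a list median of 2.25 (camera adjusted p = 1.93e-05; adjusted p = 0.0688 with an estimated correlation; lost with probes on all 21 arrays). In all, 4586 probes passed, 2445 higher and 2141 lower in testis.

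Ovary against the reference RNA was led by steroid enzymes, as Hsd3b1 stood 6.2 ± 0.60 higher (73.3-fold, n = 5 arrays) and Cyp11a1 5.61 ± 0.33 higher (48.8-fold, n = 5). Of 10 Leydig and steroidogenesis genes 7 rose, with a median of 1.10, and of 9 granulosa, theca and luteal genes 6 rose, with a median of 1.45; none of either list fell, also adjusted over the list alone. Inha was at 3.70 ± 0.22 and the receptor Scarb1, which takes up cholesterol, at 2.92 ± 0.18 (n = 4). Proliferation genes were lower: 13 of 18 fell and 0 rose (14 and 0 adjusted over the list alone), with a median of -1.03 and Pcna, the sliding clamp of DNA replication, at -1.34 ± 0.18. Camera placed the Leydig, granulosa and proliferation lists apart from the other genes at adjusted p = 1.91e-11, 1.11e-12 and 5.97e-09, and these calls held with an estimated correlation (8.00e-06, 2.04e-06 and 1.02e-04). Of 11 Sertoli cell genes 6 rose and 2 fell, with a median of 0.61, and of 8 spermatogonial genes 4 rose and 0 fell, with a median of 0.47, also adjusted over the list alone. These calls (camera adjusted p = 5.40e-05 and 4.57e-05) also held, at adjusted p = 0.0216 and 0.0421 with an estimated correlation, with Gata4 at 2.05 ± 0.21 and Foxo1 at 2.56 ± 0.21. Over the alternatives both lists kept passing, but their medians ranged from 0.51 to 1.54 and from 0.126 to 2.98. Inha and Amhr2 belong to both the Sertoli and the granulosa list, and Ccnd2 to both the spermatogonial and the granulosa list. Cyp11a1 and Cyp17a1 belong to both the Leydig and the granulosa list. The calls of these lists are therefore not independent, nor do they show which cells made the RNA. Of 68 ribosomal protein genes 1 rose and 33 fell (1 and 42 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 6.39e-07; adjusted p = 0.152 with an estimated correlation). The member that rose, Rps6, was at 0.86 ± 0.14, but 3 of its 4 probes had the opposite sign. In all, 1885 probes passed, 729 higher and 1156 lower in ovary; with all arrays scaled to 1 spread, 3515 did.

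At 15 days the testis holds germ cells up to meiosis but none of the later stages, so the comparison with adult testis addressed the genes that change as those stages appear. Collagen genes were among the most raised at 15 days: Col3a1 by 2.94 ± 0.40 (7.67-fold, n = 4), Col18a1 by 2.35 ± 0.30 (n = 4), Col1a1 by 2.34 ± 0.27 (n = 3) and Col1a2 by 2.08 ± 0.19 (n = 4). Among the most lowered were the hexokinase Hk1 at -4.73 ± 0.37 (26.5-fold, n = 4), Tekt2 at -4.68 ± 0.31 (n = 4), the glycosyltransferase Galnt3 at -4.50 ± 0.25 (n = 3) and the secreted lipocalin Lcn2 at -4.32 ± 0.29 (n = 4). The steroid enzymes Cyp17a1 and Cyp11a1 fell by 2.91 ± 0.35 and 2.02 ± 0.37 (n = 4 each). All of these genes went the same way on every array with a value. Mybbp1a had the highest ratio, 4.94 ± 1.52, but this rested on replicate 1 at 16.6, and without that array it was 1.02.

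Of 24 stroma genes 13 rose at 15 days and 2 fell, also adjusted over the list alone, with a median of 0.88. Of 7 smooth muscle genes 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 1.20 and Tpm1 at 1.43 ± 0.17 and Mylk at 1.40 ± 0.15. Both lists stood above the other genes (camera adjusted p = 8.59e-06 and 2.82e-04), and these 2 calls were the only ones of this comparison that held with an estimated correlation (adjusted p = 0.0463 for each). Of 11 Sertoli cell genes 6 rose and 0 fell, also adjusted over the list alone, with a median of 0.83. Dhh, a signal from Sertoli cells, was at 1.27 ± 0.23 and Inha at 1.24 ± 0.24. Of 8 spermatogonial genes 4 rose and 0 fell, also adjusted over the list alone, with a median of 0.99 and the X-linked Taf7l at 1.11 ± 0.18. These lists passed camera at adjusted p = 0.0122 and 0.0264, but not with an estimated correlation (adjusted p = 0.248 and 0.419), and both were lost with the arrays of run 2 alone. Of 10 Leydig and steroidogenesis genes 3 fell and 0 rose, also adjusted over the list alone (median -0.31, camera adjusted p = 0.617; median 0.0175 with probes on all 21 arrays). Genes of early meiotic prophase went both ways, 2 higher and 6 lower of 14, also adjusted over the list alone, with Sycp1 at 1.10 (picked out after its values were seen) and Syce2 at -1.34 ± 0.19 (median -0.23, camera adjusted p = 0.912). The kinases Aurkc and Plk1 were the 2 late spermatocyte genes of 7 that fell, at -2.43 ± 0.25 and -2.37 ± 0.36 (list median -0.42, camera adjusted p = 0.338). Over the alternatives that list median ranged from -2.37 to -0.0681, and the list never passed camera. By fry, on 3 of its genes, p was 4.16e-05, pointing lower. In all, 3413 probes passed, 1423 higher and 1990 lower at 15 days. With the arrays of run 2 alone 1497 did, and with those of run 5 alone 2314.

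In the testes of Spo11 knockout mice, which lack the DNA breaks that start meiotic recombination, the most raised genes included Lcn2 by 3.23 ± 0.29 (9.42-fold, n = 4), the thioredoxin Txn1 by 2.98 ± 0.26, and the antigen-presenting subunit B2m and the selenium carrier Selenop, by 2.72 ± 0.25 and 2.72 ± 0.20 (n = 4 each). The most lowered included Tekt2 at -5.73 ± 0.31 (53.0-fold, n = 4), Galnt3 at -5.09 ± 0.25 (n = 3), Ccdc136 at -5.03 ± 0.26 and Cetn4 at -5.00 ± 0.26 (n = 4 each). All of these went the same way on every array with a value. The 2 highest ratios, Grhpr at 5.42 ± 1.31 and Trim62 at 4.34 ± 1.48, each rested on replicate 2 at 15.8, and without log ratios beyond 10 they were 1.99 ± 0.32 and 0.49 ± 0.20.

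Of 11 Sertoli cell genes, 10 rose in the knockout and 0 fell, also adjusted over the list alone, with a median of 1.77. The protease Ctsl was at 2.06 ± 0.17, the secreted chaperone Clu at 2.0 ± 0.32, and Amhr2 and Wt1 at 1.84 ± 0.28 and 1.84 ± 0.27 (n = 4, and 3 for Wt1). Of 9 granulosa, theca and luteal genes, several of them also active in testis, 7 rose and 0 fell, also adjusted over the list alone, with a median of 1.77. Amhr2 and Inha stand on both the granulosa and the Sertoli list, so the results of these lists are not independent. Of 24 stroma genes 17 rose and 4 fell, also adjusted over the list alone (median 1.05), and of 7 smooth muscle genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.92). The Sertoli, granulosa, stroma and smooth muscle lists stood above the other genes by camera, at adjusted p = 1.69e-04, 0.00273, 0.00235 and 0.00386. No list call of this comparison held with an estimated correlation: for these 4 lists the adjusted p with an estimated correlation was 0.0646, 0.0767, 0.110 and 0.110. Of 6 macrophage and leukocyte genes 5 rose and 1 fell, also adjusted over the list alone, with Lyz2 at 2.02 ± 0.27 and Fcer1g at 1.90 ± 0.27. That call (camera adjusted p = 0.0419, and adjusted p = 0.0767 with an estimated correlation) was lost without knockout replicate 1 (median 1.41) or 4 (median 1.5). The correlation of the macrophage list was estimated at 0, and its unadjusted camera p went from 0.0157 to 0.0133. The rise of its adjusted p therefore came from the other lists in the adjustment.

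Of 10 Leydig and steroidogenesis genes, 7 rose in the knockout and 0 fell (7 and 1 adjusted over the list alone; median 1.05, camera adjusted p = 0.0851, and 0.00798 in a fit on these arrays alone), with Cyp11a1 at 2.19 ± 0.37 and Cyp17a1 at 1.94 ± 0.41 (n = 3). Of 14 genes of early meiotic prophase 8 fell and 1 rose, also adjusted over the list alone (median -0.51, camera adjusted p = 0.237). Syce1 was at -2.77 ± 0.60 (n = 3) and Psmc3ip at -2.25 ± 0.45, while Rad51ap2 was at 1.69 ± 0.32 (n = 3) and Sycp1, again picked out after its values were seen, at -0.18. Of 7 late spermatocyte genes 4 fell and 0 rose, also adjusted over the list alone (median -1.17, camera adjusted p = 0.0661), with Aurkc at -3.48 ± 0.25; the list passed in 3 alternatives, at adjusted p as low as 0.00179. Of 8 spermatogonial genes 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.96), with Taf7l at 1.70 ± 0.18. The camera call of this last list (adjusted p = 0.0419; adjusted p = 0.285 with an estimated correlation) was lost without knockout replicate 1 (median 0.98) or 4 (median 0.98). In all, 4214 probes passed, 2049 higher and 2165 lower in the knockout. All 4 arrays lay in run 1, which no other comparison used.

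Neither the 15 day nor the knockout testis holds the late germ cells of the adult, and their ratios were set against each other to find where they part. Lcn2 was 3.23 in the knockout and -4.32 at 15 days, a difference of 7.55 ± 0.41. The carboxylesterase Ces1d differed by 5.27 ± 0.43, Cyp17a1 by 4.85 ± 0.54, the epoxide hydrolase Ephx1 by 4.60 ± 0.25 and Cyp11a1 by 4.22 ± 0.52. Each of these 5 genes was higher on every knockout array and lower on every 15 day array with a value. In the other direction B9d1, a gene of the ciliary base, differed by -2.24 ± 0.39, being at -3.33 in the knockout and -1.09 at 15 days, and Cyp2s1 differed by -2.09 ± 0.35. The call of Cyp2s1 was lost with the 15 day arrays of run 2 alone (-2.03), and that of B9d1 with all arrays scaled to 1 spread (-1.51).

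The Leydig list was higher in the knockout than at 15 days by a median of 0.87, with 3 of 10 genes past the threshold for the difference, the granulosa list by 0.53 with 2 of 9, and the macrophage list by 1.07 with 1 of 6; none went the other way. Adjusted over the list alone these counts were 3, 3 and 4. All 3 lists stood above the other genes by camera (adjusted p = 6.19e-06, 6.24e-05 and 0.0150) and held with an estimated correlation (adjusted p = 0.00642, 0.0130 and 0.0200). For the macrophage list that correlation was estimated at 0, below the preset 0.01, so its holding was no stricter check. The macrophage call was lost without knockout replicate 1 (median 1.03) and with all arrays scaled to 1 spread (median 0.74). Restricted to probes with values on all 21 arrays, the Leydig and granulosa calls were lost (adjusted p = 0.156 and 0.475). By fry, p was 0.0392 on 3 Leydig genes and 0.186 on 5 granulosa genes. Cyp11a1 and Cyp17a1 belong to both the Leydig and the granulosa list. The Sertoli list lay 0.74 higher, with 1 of 11 genes past the threshold, namely Ctsl (4 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.0532 with an estimated correlation; lost with all arrays scaled to 1 spread). Among lists that lay lower in the knockout were proliferation, by a median of -0.44 over 18 genes (camera adjusted p = 0.00256; adjusted p = 0.0532 with an estimated correlation), and early meiotic prophase, by -0.48 over 14 genes (camera adjusted p = 0.0317; adjusted p = 0.377 with an estimated correlation). The late spermatocyte list, at a median of -0.61 over 7 genes, did not pass (camera adjusted p = 0.0547), but did in 6 alternatives, at adjusted p as low as 8.49e-04. No gene of these 3 lists passed the threshold in limma, also adjusted over the list alone. The early meiotic call was lost without knockout replicates 1 (-0.52) or 4 (-0.43), without 15 day replicate 2 (-0.41), and in 4 other alternatives.

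Across genes, the knockout and 15 day ratios correlated at r = 0.864 (rho = 0.858), and 95.2% of the genes called in the knockout had the same sign at 15 days. Both comparisons called 690 genes higher and 1095 lower, where independent lists would share 224.2 and 401.9, and 17 genes were called in opposite directions, 15 of them higher in the knockout. The groups shared no array, and whether they shared RNA was not stated. Both ratios were taken over wild type testis. Anything particular to that tissue enters both with the same sign and can raise the correlation and the overlap. The difference passed for 167 probes, 132 higher and 35 lower in the knockout. With the 15 day arrays of run 2 alone it passed for 65 probes, and with those of run 5 alone for 40. The knockout arrays were all in run 1 and the 15 day arrays were not, so run and comparison cannot be told apart. Without 1 array at a time the count ranged from 74 to 172; it fell to 98 and 107 without knockout replicates 1 and 3, and to 94, 85, 77 and 74 without 15 day replicates 1, 2, 3 and 4.

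**Figure D2:**
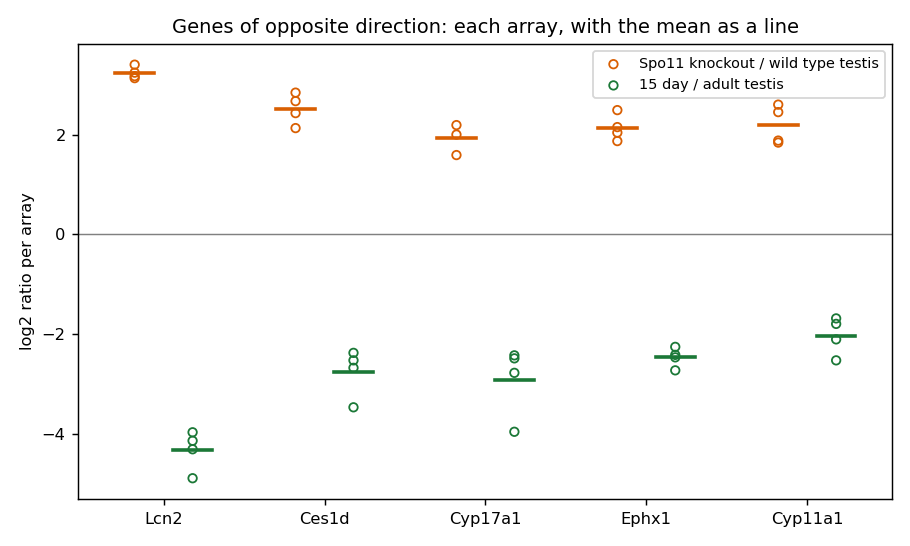
Log2 ratio on each array (circles) and mean (lines) of Lcn2, Ces1d, Cyp17a1, Ephx1 and Cyp11a1 in Spo11 knockout over wild type testis and in 15 day over adult testis. The knockout arrays lie between 1.59 and 3.4 and the 15 day arrays between -4.88 and -1.68.

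X-linked genes, most of which are silenced in male germ cells during meiosis, were set against autosomal genes in each comparison. In the knockout, 67 of 119 X-linked genes rose (56.3%) against 26.0% of 4302 autosomal genes, an odds ratio of 3.67 (95% CI 2.50 to 5.41, Fisher exact adjusted p = 8.71e-11). Fewer fell, 13.4% against 31.7% (odds ratio 0.334, which was 0.183 without knockout replicate 1). At 15 days 40.3% rose against 17.9% (odds ratio 3.11, adjusted p = 1.56e-07), and in ovary against testis 42.9% rose against 22.2% (odds ratio 2.62, adjusted p = 3.86e-06). Testis against the reference showed the reverse, as 47.9% of X-linked genes fell against 25.8% of autosomal genes (odds ratio 2.65, adjusted p = 1.91e-06). Ovary against the reference showed no call, with 15.1% higher against 9.81% (odds ratio 1.64, adjusted p = 0.0725) and medians of -0.0735 and -0.0710 (permutation p = 0.956). The odds ratio there was 1.87 without ovary against reference replicate 5, which passed (adjusted p = 0.0366). It also passed without centring (1.77), with array run as a random block (1.75) and with 1 probe per gene (1.75).

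The raised X-linked genes included the actin-binding Tmsb4x at 2.27 ± 0.14 and Sh3bgrl at 2.34 ± 0.27 in the knockout, and Fundc1 at 2.11 ± 0.21 and Maged1 at 1.62 ± 0.19 at 15 days. Taf9b at 2.60 ± 0.15 and Sh3bgrl at 2.89 ± 0.23 rose in ovary. Some X-linked genes went the other way: Tspan6 was at -3.40 ± 0.27 in the knockout and -3.35 ± 0.27 at 15 days (n = 3 each), and Plac1 at -2.17 ± 0.19 in ovary. The X-linked median lay above that of the autosomal genes by 0.722 in ovary against testis, 0.579 at 15 days and 0.861 in the knockout. The permutation p was 1e-05 in each, the smallest that the permutations can give. For each of the 19 autosomes the median less that of the other autosomes lay between -0.204 and 0.205 in these 3 comparisons. Of 10 X-linked parents of testis retrogenes, 7 rose and 2 fell in ovary, also adjusted over the list alone, with Pdha1 at 2.88 ± 0.55 and Pgk1 at 1.83 ± 0.28 (n = 3 each; list median 1.20, camera adjusted p = 0.0267; adjusted p = 0.0848 with an estimated correlation). In the knockout minus 15 day contrast 8 X-linked genes were higher (6.72% against 2.09%, odds ratio 3.37, adjusted p = 0.00577), a call lost in 9 alternatives. These included leaving out knockout replicate 2 (1.99) and 15 day replicates 2 (1.71) and 3 (1.58), and the 15 day arrays of run 2 (0.903) or run 5 (0) alone.

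**Figure D3:**
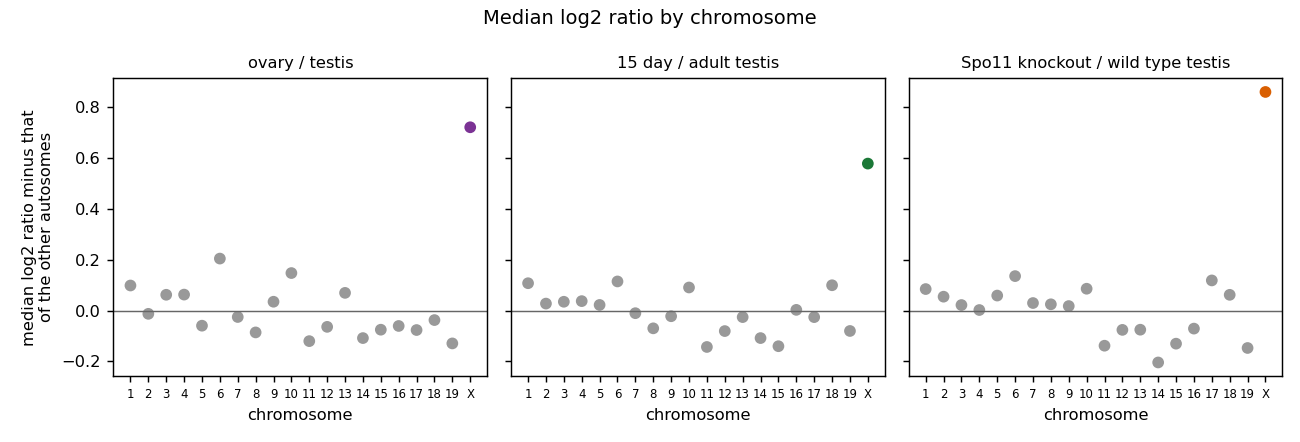
Median log2 ratio of the genes of each chromosome less that of the genes of the other autosomes (y axis), for ovary over testis, 15 day over adult testis and Spo11 knockout over wild type testis. The X chromosome (coloured) lies at 0.722, 0.579 and 0.861, above all 19 autosomes (grey) in each panel.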

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

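The tests of array spread, of the run of the 15 day arrays, of the loss of germ cells and of log ratios beyond 10 were chosen after the results were seen. What the tests of the X-linked genes would show was written down before their values were seen, though after the pattern itself.

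The largest differences, knockout minus 15 day, were those of Lcn2 (7.55), Ces1d (5.27), Cyp17a1 (4.85), Ephx1 (4.60) and Cyp11a1 (4.22), which rose in the knockout and fell at 15 days. Different spread of the arrays was argued against, because it cannot turn a sign, 5 of the 5 genes lay above 0 on every knockout array and below 0 on every 15 day array, as they were picked to do, and the differences stayed between 3.92 and 7.28 with all arrays scaled to 1 spread; so was the run of the 15 day arrays, as 5 of the 5 passed with either run, while run 1 and the knockout cannot be told apart. A loss of germ cells that raises all other cell types alike was also tested at 15 days. There the 8 genes of the Leydig and steroidogenesis list outside the 5 had a median of -0.0206 against 0.785 for 49 other somatic genes. The difference was -0.806 (permutation over genes, which are not independent, p = 0.0233). The 8 genes include Acat1, Dhcr7, Hmgcs1, Idi1 and Sqle, which are not particular to Leydig cells, so this difference does not decide the question. In the knockout these 8 genes also lay lower, by a difference of -0.407 (0.836 against 1.24; permutation p = 0.253), so the lag was not shown to be particular to 15 days. Cyp11a1 and Cyp17a1 are made by Leydig cells, and fewer adult-type Leydig cells at 15 days than in the knockout stays an untested hypothesis, as the labels do not give the age of the knockout mice.

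The X-linked excess in the knockout (0.861) and at 15 days (0.579) could come from a change in the mixture of cells, if tissue-biased genes are unevenly spread over chromosomes. After the trend of each ratio on the ovary to testis ratio was removed, the knockout excess fell to 0.133. That was narrowly above the highest autosome, at 0.113 (permutation p = 0.0342). By the rule written beforehand this value speaks against mixture as the whole cause. The ovary to testis ratio is only a stand-in for the cell mixture of a knockout testis, however. So narrow a margin therefore cannot exclude mixture, which could account for most or all of the excess. At 15 days the excess became -0.0557, within the autosomes' range of -0.0736 to 0.0959 (permutation p = 0.355), so mixture stays open there too. Uneven gene content of chromosomes in general was argued against, because the largest distance of an autosome from 0 in the knockout was 0.204 (chromosome 14, at -0.204). The autosomes cannot show whether the X itself holds an unusual set of genes, which was not tested. X-linked genes themselves stood 0.722 higher in ovary than in testis, so the removed trend also carries any X-specific silencing in meiotic cells, which stays open and was not tested apart from mixture.

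Grhpr, Trim62, Mybbp1a and Nlrp14 were among the largest changes but had standard errors above 1. Single arrays near the full scale of the scanner were the candidate cause, and with log ratios beyond 10 set to missing Grhpr went from 5.42 to 1.99, Trim62 from 4.34 to 0.49 and Mybbp1a from 4.94 to 1.02, each still past the threshold. That 3 of these 3 genes moved by more than 1 follows from arithmetic, as each had 1 array near 16, so whether those arrays hold a fault or a true value stays open. For Nlrp14, at -4.89, this cause was argued against, because its largest log ratio on any array was 6.69 in size, and its call was lost without 15 day replicate 3 (-4.44).

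Of the 117 named genes whose knockout and 15 day effects were compared, 21 differed past the threshold in the test of the difference itself. Some of these genes were named for the size of that difference, so the share is raised by the choice. Over all genes, 119 of 4465 differed. Among the other genes that differed, the knockout minus 15 day value was 2.41 for Ecm1, 2.38 for Selenop, 1.87 for B2m, 1.62 for Txn1, 1.51 for Fcer1g, 1.39 for Sat1, 1.23 for Ctsl, 0.80 for Tmsb4x and 0.73 for Eif1ax. It was -1.01 for Col1a2, -1.52 for Cetn4, -1.69 for Rsph1, -1.75 for Parn, -1.91 for Gmfb, -2.09 for Cyp2s1 and -2.24 for B9d1. With the 15 day arrays of run 2 alone Cyp2s1, Gmfb and Rsph1 did not pass (-2.03, -2.09 and -1.90), and with those of run 5 alone Gmfb, Parn and Rsph1 did not (-1.73, -1.49 and -1.48); B9d1 passed with both, at -3.29 and -1.76, but not with all arrays scaled to 1 spread (-1.51). The values of Rsph1, Gmfb and Parn did not pass without certain single arrays, Parn only without 15 day replicate 1 (-1.55). Gmfb was lost without knockout replicate 3 (-1.25) and without 15 day replicates 2 (-1.59), 3 (-1.99) and 4 (-1.97). Rsph1 was lost without knockout replicates 1 (-1.53), 2 (-1.77), 3 (-1.72) and 4 (-1.75) and without 15 day replicates 2 (-1.28), 3 (-1.91) and 4 (-1.62).

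In 30 of 319 sets of 4 or 5 arrays (9.40%, where chance gives about 5%), the gap of 1 array to its nearest neighbour took an unusually large share of the whole range. All 6 such genes in ovary against testis pointed to replicate 1, the array with the fewest values: Rgs2 (share 0.919), Plk1 (0.914), Gm9 (0.902), Hk1 (0.873), Kpna2 (0.873) and Gtsf1 (0.846). At 15 days these were Mybbp1a (0.987), Plac1 (0.905), Tekt2 (0.875), Rps13 (0.873), Zp2 (0.852), C1qc (0.847) and Myl9 (0.846). Rps13 was -1.22 at 15 days and -0.58 without replicate 2. In the knockout they were Trim62 (0.977), Eci1 (0.921), Tmsb4x (0.884), Nr5a1 (0.881), Grhpr (0.862), Gtsf1 (0.860) and Htatsf1 (0.857). In testis against the reference they were Rpl39l (0.914), Ccdc65 (0.904), Uqcrc1 (0.888), Plk1 (0.883), Cdt1 (0.857), Hsd3b1 (0.856) and Hbb-y (0.844), and in ovary against the reference Myl9 (0.860), Gata4 (0.754) and Ndrg1 (0.752). Plk1 was 1.83 in testis against the reference and 1.11 without replicate 2.

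Other signs of the arrays within a comparison, or other divisions of the arrays between the groups of a contrast, tested whether chance could give as many called probes. For the difference of knockout and 15 day effects, 1 of 35 assignments, the real one, gave as many as 167 probes. The highest other gave 2, so a chance division of these arrays was argued against. The knockout and 15 day arrays lay in different runs, so the real division also divides the runs, and the count cannot tell the 2 apart. For ovary against testis through the reference, 1 of 100 gave as many as 3432 and the highest other gave 2452. A chance division of those arrays was argued against there too, though another division still gave most of that count. The arrays of a comparison may be technical repeats, so chance between animals or extracts was not tested in either contrast. The remaining comparisons had too few assignments, 8 or 16, for a share under 0.05. Their real and highest other counts were 4443 and 2786 for ovary against testis, 3413 and 460 at 15 days, 4214 and 560 in the knockout, 4586 and 432 for testis against the reference, and 1885 and 463 for ovary against the reference.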

How the results depend on the processing

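The alternatives with log ratios beyond 10 set to missing and with the 15 day arrays of 1 run were chosen after seeing the data. Over 35 settings, 5376 of 5568 called values of named genes kept their direction and call, 189 lost the call and 3 reversed; of 665 list calls 618 were kept, 46 lost and 1 reversed, while 39 were gained, and of 187 X-linked calls 178 were kept, 8 lost and 1 reversed, while 4 were gained. Requiring values on all 21 arrays left 3126 probes to test, and so fewer calls: 2030 for ovary against testis, 1616 at 15 days, 1862 in the knockout, 2068 and 889 for testis and ovary against the reference, 1648 through the reference, and 78 for knockout minus 15 day. With all arrays scaled to 1 spread, ovary against the reference gave 3515 probes, knockout minus 15 day 81, and direct minus indirect 64. Knockout minus 15 day gave 110 probes when fitted on its own arrays, 282 with 1 value in each group (63.1% higher), 254 with array run as a random block, 65 with run 2 (66.2% higher) and 40 with run 5. Leaving out arrays gave 74 to 172 (78.7% to 89.2% higher). With the run block, the correlation within runs was estimated at -0.0507 over probes and -0.056 over genes. A value below 0 cannot stand for a shared effect of run. Calls gained with that block therefore do not show that results hold once run is allowed for. The 15 day count was 1497 with run 2, from fewer arrays, and direct minus indirect was 1 with 1 value in each group. The odds ratio of X-linked genes being higher in knockout minus 15 day was 1.37 with scaling, 1.81 on its own arrays, 1.88 on all 21 arrays, 2.28 with a 2-fold minimum, 0.903 (reversed) with run 2, 0 with run 5, and 1.58 to 3.89 leaving out arrays. For ovary against the reference it passed at 1.77 without centring, 1.75 with the run block and 1.75 with 1 probe per gene, and ranged from 1.47 to 1.87 leaving out arrays. Among genes and lists the reversals came with other probes: Rps6 in ovary against the reference from 0.86 to -0.53 (all 21 arrays) and -0.74 (1 probe), Ccnd2 in ovary against testis from 1.30 to -0.09, and the granulosa list from 1.30 to -0.085 (1 probe). Where no reason is given, the cause was not tested. No paired analysis was possible because the labels carry no replicate numbers that pair arrays of different comparisons. Signal over background was not used here, so its limits on dim probes are unknown.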

Other observations

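As a list, respiratory chain genes did not pass camera in ovary against testis, at 15 days or in the knockout. By fry, on 18 of them, p was 0.00419, 0.0063 and 0.0809 in these comparisons, each pointing lower. Of all 4465 genes, 1025 rose and 1642 fell in ovary against testis. Of 30 genes of the mitochondrial respiratory chain, 2 rose and 10 fell in ovary against testis (1 and 10 adjusted over the list alone; median -0.26, camera adjusted p = 0.767). Uqcrc1 was at -1.73 ± 0.21 and Ndufv2 at -1.48 ± 0.18, whereas Cox8a was at 1.60 ± 0.30 (n = 3). At 15 days 3 rose and 9 fell (1 and 9 adjusted over the list alone; median -0.35, camera adjusted p = 0.545), with Cox7a2 at -1.79 ± 0.23 and cytochrome c, Cycs, at 1.54 ± 0.23. In the knockout 3 rose and 7 fell, also adjusted over the list alone; the median of -0.0169 became 0.0781 without centring each array (camera adjusted p = 0.871). Of the 2 sperm glycolysis genes tested, Hk1 fell in ovary, at 15 days and in the knockout, at -3.60 ± 0.37, -4.73 ± 0.37 and -4.93 ± 0.43, while Pkm was at -0.29, -0.23 and 0.24. In both comparisons of testes, Rpl39l, which testis germ cells express, was lowered, at -1.82 ± 0.29 at 15 days and -2.13 ± 0.29 in the knockout, where its X-linked relative Rpl39 was at 1.51 ± 0.28.

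Few markers of other tissues were tested, for example 5 of 16 oviduct and ciliated epithelium genes and 1 of 14 adipose genes. Of 5 oviduct and ciliated epithelium genes 3 rose and 1 fell in ovary (3 and 2 adjusted over the list alone; median 1.51), with Krt18 at 2.30 ± 0.18 and Msln at 2.04 ± 0.34. The camera call (adjusted p = 0.0401, and adjusted p = 0.0708 with an estimated correlation) was lost without replicate 1 (median 1.5). The correlation of that list was estimated at 0, and its unadjusted camera p went from 0.02 to 0.0177. The rise of its adjusted p therefore came from the other lists in the adjustment. Of 3 blood genes 2 rose and 1 fell, also adjusted over the list alone (median 0.58, camera adjusted p = 0.604), with Slc4a1 at -0.96 ± 0.22. The adipose list was represented by Lpl, at 1.78 ± 0.32 in ovary, and the endothelium list by Cd34, at -0.79 ± 0.23. Proliferation genes fell in 10 of 18 cases and rose in 1, also adjusted over the list alone (median -0.61), with Aurka at -3.02 ± 0.21 and Mcm7 at -2.30 ± 0.23. That camera call (adjusted p = 0.0494; adjusted p = 0.197 with an estimated correlation) was lost without replicates 1 (median -0.71) or 3 (-0.52). The ribosomal list at 15 days had 18 higher and 9 lower of 68 (17 and 9 adjusted over the list alone), with a median of 0.12. Its call (camera adjusted p = 0.0352; adjusted p = 0.558 with an estimated correlation) was lost without replicates 2 (median 0.06) or 4 (0.08). In the knockout the ribosomal list had 24 higher and 12 lower (22 and 11 adjusted over the list alone; median 0.16, camera adjusted p = 0.0661, and 0.0491 with probes on all 21 arrays). The epididymis list and the autosomal retrogenes had 0 tested members.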
